A study of Mus musculus with 4 samples.

How the data were processed

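RNA was measured in 4 samples of mouse bone marrow-derived macrophages, 1 for each genotype (WT, or knockout of both Hes1 and Hey1, DKO) and treatment (none, or 2 ng/ml LPS for 3 h). Per the labels' protocols, cells were cultured for 5 days in medium with 10% serum and 10% L929 supernatant, and total RNA was purified on columns, amplified and labelled with biotin before hybridisation to Affymetrix mouse arrays of 45101 probe sets. A probe set is a group of short probes that together read 1 transcript.

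The deposited table gives 1 intensity per probe set and array on a linear scale. From the values, the mean of each array after trimming 2% at either end was 500.0, so the authors' intensities had been scaled to a common trimmed mean. The tool that made them is not given in the sources used here. Such scaling fixes the mean of bright signal and leaves the level of dim probe sets free, so counts of dim genes depend on it. Background was read from 27 bacterial control probe sets, which serve as negative controls only if no matching transcript was added to the samples. The signal over background limits what can be seen: these controls reached at most 46.0 units, close to the floor below. That maximum was on the WT array with LPS, and the other arrays reached at most 32.7. The medians of these controls were far lower, 4.64 to 6.87 units.

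The 64 control probe sets were left out. Of the others, 34945 had 1 gene in the platform annotation, 932 had several and named none here, and 9160 were not listed with a gene and stayed unnamed. Gene symbols were updated through Entrez identifiers with a RefSeq table of assembly GRCm38.p6 for 34741 probe sets, and 204 kept the annotation's symbol. That table served only for names and for the order of genes along chromosomes, and the array annotation names no build. A gene's value is that of its probe set with the highest mean over the 4 arrays.

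Values under the median of all probe sets pooled over the arrays, 52.9 units, were set to that floor before log2 was taken. A difference with 1 array under the floor is therefore a bound, printed as at least N-fold, a gene under the floor on both arrays has no difference, and list medians hold such genes at their bound. With 1 array per group no comparison was tested. A fit of genotype and LPS as additive terms would take the difference of LPS effects, itself a result here, as its error, and was not run. Each comparison is the log2 difference of 2 arrays, or of the LPS effects of the 2 genotypes, and genes were counted at a fixed threshold of 2-fold. For genes with at least 2 probe sets above the floor on all arrays, the differences read by the 2 brightest probe sets were a median of 0.26 apart for the LPS effect in WT cells and 0.20 in DKO cells, over 4709 genes. This describes agreement within the arrays and not variation between cultures.

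Before the data were examined, 27 gene lists, the comparisons, the floor, the threshold, the alternatives and the rule for named genes were fixed. The lists held inflammatory cytokines, chemokines, interferon and interferon-stimulated genes, NF-kB feedback regulators, immediate early transcription factors, alternative activation, the Notch pathway, antimicrobial and lipid-mediator effectors, antigen presentation, Toll-like receptor signalling, macrophage identity, cell cycle, cholesterol synthesis, LXR targets, glycolysis and hypoxia, stress responses, Nrf2 targets, reference and sex-linked genes, and markers of other cell types. Of their 560 entries 510 matched a measured gene. A list's median was set against 10000 random lists of the same size matched on mean expression in 20 bins, which describes these arrays only.

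The rule for named genes took, per comparison, the 10 genes with the largest difference in each direction among genes above the floor on every array, the 5 largest bounds in each direction, the 4 members of each list with the largest difference and any member past 2-fold, and Hes1 and Hey1. For DKO against WT with LPS it also took the 10 largest differences in each direction among genes induced by LPS. The largest differences and bounds left out unnamed transcripts and genes with another probe set going the other way. Genes named outside this rule are said to be so. Of named genes past 2-fold with another probe set above the floor on all arrays compared, 10 of 44 for LPS in WT, 8 of 51 for LPS in DKO and 5 of 8 for the difference of LPS effects had such a probe set short of 2-fold in the same direction.

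Alternatives were equal array medians, quantile normalization, cyclic loess, floors at the 35th and 65th percentile, no floor with an offset of 16 units, the median of a gene's probe sets, probe sets shared between transcripts left out, and thresholds of 1.5-fold and 3-fold. Genes for the comparison of LPS induction were also chosen by 1 genotype alone, and, added after seeing the data, chosen on their brightest probe set and measured on the second brightest. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for the normalizations.

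The steps were tested on simulated data. For DKO against WT with LPS, arrays were drawn from the real mean intensities with the scatter between the untreated WT and DKO arrays, over 11341 genes. That scatter holds differences between the genotypes, and it was drawn for each probe set independently. The changed genes were drawn only from genes of middle intensity, with a mean of at least 200 units on the untreated arrays. Recovery of changes in dimmer genes was therefore not simulated. Of 50 genes changed 3-fold, 94% were called at 2-fold or more in the right direction, of 50 changed 4-fold and of 50 changed 8-fold 100%, and of 50 changed 1.5-fold 4%. Among 11141 unchanged genes, 126 were called, a number set by that scatter and not a rate of false calls between replicates. Of 200 unchanged lists of 20 genes, 6% lay outside the central 95% of random lists, and 98% of 50 lists shifted by 0.3 log2 units lay above it. As their genes were drawn independently, these lists do not cover lists whose members vary together.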

Results

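Microarrays measured the RNA of bone marrow-derived macrophages from C57BL/6 mice. These cells are grown from bone marrow precursors, here for 5 days with 10% supernatant of L929 cells, a source of macrophage colony-stimulating factor. The cells were wild type (WT) or carried knockouts of both Hes1 and Hey1 (DKO), which encode basic helix-loop-helix transcriptional repressors known as targets of Notch signalling. Cells of each genotype were left untreated or received 2 ng/ml of lipopolysaccharide (LPS), the bacterial ligand of the Toll-like receptor TLR4, for 3 h. The study set out to find inflammatory genes regulated by Hes1 and Hey1 in macrophages.

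There were 4 groups with 1 array each, so there are no replicates and no difference below has a replicate check. The number of arrays limits the precision, and no p-value or error is given. A gene is called higher or lower where its intensities differed by at least 2-fold between arrays. Each array gave 45101 probe set intensities, and 18193 genes were measured, of which 11829 lay above the floor of 52.9 intensity units on at least 1 array and 9982 on all 4. Median intensities were 59.1 on the untreated WT array, 50.9 on the WT array with LPS, 51.0 on the untreated DKO array and 50.8 on the DKO array with LPS. Among 19615 probe sets under the floor on all arrays, the untreated WT array was brighter than the others by a median log2 ratio of 0.24, against 0.015 among 9369 probe sets of at least 500 units on all arrays. Among 16053 probe sets of neither kind it was brighter by 0.23.

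The targeted genes were dim on all arrays. The single probe set of Hes1 gave 45.4 in untreated WT cells, 26.7 in WT cells with LPS, 2.14 in untreated DKO cells and 5.80 in DKO cells with LPS, all under the floor. The single probe set of Hey1 gave 57.2, 17.3, 9.17 and 10.2 in the same order, above the floor in untreated WT cells only. Both genes read lower on both DKO arrays than on either WT array, but values under the floor have no reliable order. Whether the probe sets lie in the deleted parts is not given in the sources used here, so the levels check the genotype labels only weakly.

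The 2 comparisons of LPS with no treatment ask which genes respond to LPS in each genotype. In WT cells, transcripts of several inflammatory cytokines and chemokines were far higher with LPS. Tnf was 121-fold higher, from 122 to 14788 units, and Cxcl2 108-fold higher. Genes under the floor without LPS gave bounds: Cxcl3 was at least 172-fold higher, Cxcl1 at least 128-fold, Ptgs2, the inducible prostaglandin synthase, at least 121-fold, and Il1b at least 70.3-fold. Acod1, which makes itaconate, was 53.0-fold higher, the fatty acid receptor gene Gpr84 42.6-fold and the costimulatory receptor gene Cd40 22.4-fold.

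Lower with LPS in WT cells were Rgs2, a regulator of G protein signalling (log2 difference -2.65), the thrombomodulin gene Thbd (-2.45), the ubiquitin ligase gene Rnf144b (-2.45), Enc1 (-2.42) and Sesn1 (-2.25). The transcription factor gene Sox4 was at least 13.4-fold lower. Of 11491 genes above the floor, 386 were higher and 392 lower. Among genes with a mean of at least 500 units, 259 were higher and 123 lower. The split rests on scaling: it was 520 higher and 194 lower with array medians set equal, 429 and 256 after quantile normalization, and 447 and 223 after loess. Equal medians moved the median difference of all genes from -0.086 to 0.12.

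Inflammatory lists held many of the genes higher with LPS in WT cells. Of 15 measured inflammatory cytokines, 11 were higher and 0 lower, among them Il6 (at least 24.4-fold), Tnfsf9 (20.7-fold) and Csf1 (7.32-fold). Of 18 chemokines, 14 were higher and 0 lower, including Cxcl10 (21.5-fold), Ccl3 (17.7-fold) and Ccl2 (15.4-fold). NF-kB feedback regulators, which dampen inflammatory signalling or belong to the NF-kB family, were higher in 25 of 27 members, led by Nfkbie (32.2-fold), Socs3 (27.3-fold), Tnfaip3 (16.6-fold) and Nfkbiz (14.6-fold). Their list median was 2.07, against -0.19 to 0.12 for the central 95% of random lists matched on expression. Antimicrobial and lipid-mediator effectors were higher in 12 of 22, with the acute phase gene Saa3 at 9.51-fold and Clec4e at 12.6-fold.

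In Toll-like receptor signalling, 7 of 27 members were higher with LPS in WT cells, including the inflammasome gene Nlrp3 (17.1-fold) and Tlr2 (8.52-fold), and 1 was lower, Tlr8 (-1.01). Interferon and interferon-stimulated genes were higher in 7 of 39 and lower in 1, with Irf1 at 5.50-fold and Rsad2 at 3.24-fold higher and Ifi204 at -1.13. Immediate early transcription factors split into 6 higher, led by Ets2 (26.3-fold), and 1 lower, Klf4 (-1.81), among 21. In the Notch pathway 2 of 28 members were higher, the ligand gene Jag1 (10.8-fold) and the transcription factor gene Rbpj (3.20-fold), and the list median of 0.068 lay inside the random range of -0.25 to 0.10.

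In WT cells macrophage identity genes gave 2 higher with LPS, Msr1 among them (2.15-fold), and 3 lower of 25, the efferocytosis receptor gene Mertk (-1.70), the chemokine receptor gene Ccr2 (-1.64) and Maf (-1.37). The median of this list was 0.27, above its random range of -0.023 to 0.23. In unfolded protein and integrated stress responses 3 of 18 were higher, with the cystine transporter gene Slc7a11 at 8.29-fold, and 4 of 11 Nrf2 targets were higher, including Sqstm1 (2.69-fold). LXR targets and lipid efflux genes gave 1 higher, the cholesterol exporter gene Abca1 (2.98-fold), and 2 lower of 12. In glycolysis and the hypoxia response 2 of 18 were higher, Slc2a1 (2.85-fold) and Hif1a (2.44-fold). In antigen presentation and costimulation 3 of 21 were higher, with Icosl at 7.19-fold. None of 16 cholesterol synthesis genes passed 2-fold, although their list median of 0.20 lay above the random range of -0.30 to 0.12. In DKO cells it was 0.14, against -0.34 to 0.10. The alternative activation list gave 1 higher and 1 lower of 16. Of 27 cell cycle genes 1 was lower, the replication licensing gene Cdc6 (-1.06), and the list median was -0.14, against -0.11 to 0.16 for random lists. With array medians set equal, which moves the median of all genes as given above, it was 0.079, against 0.091 to 0.37.

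In DKO cells, transcripts of several inflammatory mediators were likewise far higher with LPS. Ptgs2 was 175-fold higher with LPS, Cxcl2 169.9-fold, Tnf 158-fold, Acod1 124-fold and Gpr84 119.6-fold. Bounds were at least 287-fold for Cxcl1, at least 235-fold for Cxcl3, at least 143-fold for Il1b, at least 119-fold for Socs3 and at least 47.3-fold for Il6. The membrane metalloprotease gene Mmp14 was 51.3-fold higher and Saa3 46.7-fold. Among the genes lowered most were Rnf144b (log2 difference -3.63), the arrestin-domain gene Arrdc3 (-3.29), Enc1 (-3.22), Rgs2 (-3.15), Gpr183 (-3.08), a receptor for oxysterols, and Fbxo32 (-2.97), with Klf4 8.02-fold lower and Sox4 at least 16.8-fold lower.

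Of 11241 genes above the floor in DKO cells, 524 were higher and 536 lower, or 339 and 226 among genes with a mean of at least 500 units. Higher in both genotypes were 338 genes, from 384 in WT and 517 in DKO cells among 10903 genes above the floor in both comparisons, where independent lists would share 18.2. Lower in both were 221, from 390 and 535, where independent lists would share 19.1. Across 9982 genes the 2 LPS effects correlated with Pearson's r of 0.84 and Spearman's rho of 0.70, and genes are not independent replicates. The comparisons share no array.

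**Figure D1:**
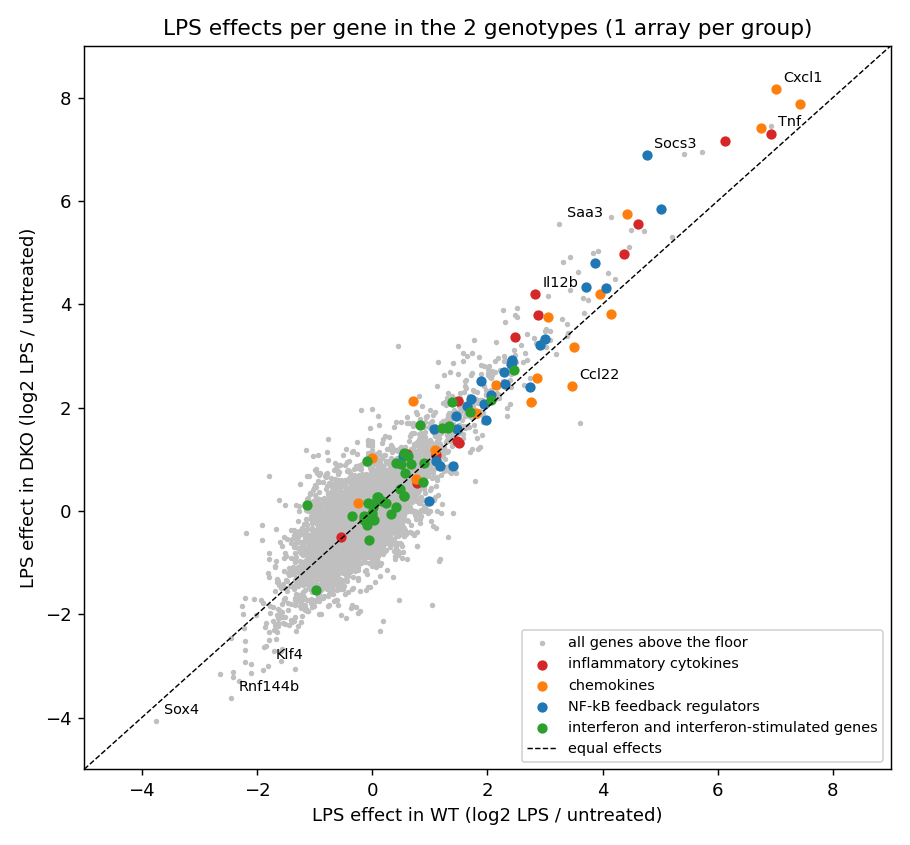
Each point is a gene, with the log2 ratio of LPS to untreated in WT cells on the x axis and in DKO cells on the y axis, from 1 array per group; coloured points are members of 4 fixed gene lists and the dashed line marks equal effects. Most induced cytokines, chemokines and NF-kB feedback regulators lie above the line, while Ccl22 lies below it (-1.06 in DKO against WT cells with LPS).

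By list, 12 of 15 cytokines, 16 of 19 chemokines and 23 of 27 NF-kB feedback regulators were higher with LPS in DKO cells and none of their members was lower. Antimicrobial and lipid-mediator effectors were higher in 11 of 24, Toll-like receptor signalling in 8 of 26, and antigen presentation in 3 of 21. Interferon-stimulated genes were higher in 10 of 40, with Mx1 at 4.33-fold, and 1 was lower, the transcription factor gene Irf8 (-1.53). Stress responses were higher in 6 of 18, with Slc7a11 at a log2 difference of 4.17 and Chac1 at 6.17-fold, and Nrf2 targets in 5 of 11. Immediate early genes gave 5 higher and 2 lower of 22, the latter Klf4 and Jun (-1.61). Macrophage identity genes gave 2 higher and 3 lower of 25, the lower ones again including Mertk (-2.28) and Ccr2 (-2.01). In the Notch pathway 3 were higher, with Jag1 at 19.3-fold, and 1 lower of 30.

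The comparison of DKO with WT cells without LPS asks what the loss of both genes changes at rest. Tmem87a was 16.5-fold higher in DKO cells, 1078 against 65.5 units. Scd1, a fatty acid desaturase gene, was 4.56-fold higher, Sh3tc1 4.68-fold, the adhesion gene Nectin3 3.11-fold, the chemokine gene Cxcl14 2.97-fold, Dcbld2 2.86-fold and Tbc1d23 2.82-fold. Lower in DKO cells were the glutathione transferase gene Gsta3 (log2 difference -2.23), Rgcc (-2.19), the protease inhibitor gene Spint1 (-2.07), the stress-induced pseudokinase gene Trib3 (-1.90), Chac1 (-1.65), which degrades glutathione, the kinase gene Src (-1.64) and Saa3 (-1.59). Socs3 was at least 3.70-fold lower and the secreted protease gene Htra1 at least 4.22-fold lower, while Mx2 was at least 2.18-fold higher. Of 7 named genes past 2-fold with another probe set above the floor on both arrays, 4 had such a probe set short of 2-fold: Cxcl14 (1.14-fold), Tbc1d23 (1.14-fold for 1 of 2), Rgcc (1.34-fold lower) and Socs3 (1.79-fold lower). The other probe set of Scd1, under the floor in WT cells, gave at least 1.51-fold.

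Few genes passed 2-fold in this comparison. Of 11380 genes above the floor, 53 were higher and 112 lower in DKO cells, or 18 and 29 among genes with a mean of at least 500 units. The split was 97 higher and 43 lower with array medians set equal, 66 and 71 after quantile normalization, and 64 and 68 after loess, and equal medians moved the median of all genes from -0.017 to 0.19. The probe sets that were brighter on the untreated WT array, as given above, enter this comparison.

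Macrophage identity genes had a list median of 0.29 in untreated DKO cells, against -0.003 to 0.17 for random lists, with 1 of 25 members higher, the complement gene C1qa (2.72-fold), and C1qc at 1.68-fold and the apolipoprotein gene Apoe at 1.67-fold. The LXR list stood at 0.34 against -0.10 to 0.17, with 1 of 12 members higher, Scd1, and Abca1 at 1.67-fold. Interferon-stimulated genes had a median of 0.25 against -0.052 to 0.10, with 1 of 39 higher, Mx2. In that list Zbp1 stood at 1.94-fold and Irf7 at 1.73-fold. The alternative activation list had a median of 0.18 against -0.13 to 0.15, with 1 of 17 higher, the folate receptor gene Folr2 (2.61-fold).

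On the other side, unfolded protein and integrated stress response genes had a median of -0.27 in untreated DKO cells against -0.10 to 0.14, with 2 of 18 lower, Trib3 and Chac1. Nrf2 targets had a median of -0.27 against -0.082 to 0.20, with none of 11 passing 2-fold. NF-kB feedback regulators stood at -0.14 against -0.084 to 0.11, and with array medians set equal, which raises all genes here, at 0.076 against 0.13 to 0.32. Of 26 members 1 was lower, Socs3. Cell cycle genes stood at -0.080 against -0.049 to 0.13, or at 0.13 against 0.16 to 0.34 with array medians set equal, and none of 27 passed 2-fold. In this comparison 3 of 16 antimicrobial and lipid-mediator effectors were lower, Saa3, Plaur (-1.09) and Acod1 (-1.09), and 1 of 13 chemokines was lower, Cxcl10 (-1.07). None of 7 cytokines and none of 29 Notch pathway genes passed 2-fold.

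The comparison of DKO with WT cells under LPS asks which inflammatory genes the loss of both genes changes. Several induced genes read higher in DKO cells: Il12b, the shared subunit of interleukins 12 and 23, was 2.59-fold higher at 971 against 375 units, Il1b 2.03-fold, Cxcl1 2.24-fold, Ccl12 2.67-fold and Cd40 2.28-fold. Il6 read 2501 against 1291 units, short of the 2-fold mark at 1.94-fold. Among other induced genes, the formyl peptide receptor gene Fpr2 was 2.78-fold higher, the Wnt receptor gene Fzd1 3.65-fold, the lipid phosphatase gene Plpp1 3.37-fold, the integrin gene Itgb8 2.54-fold, and Rgs16 2.53-fold, and the scavenger receptor gene Marco was higher by a log2 difference of 1.32. Induced genes that were lower in DKO cells were Vegfc (log2 difference -1.21), Met (-1.08), the chemokine gene Ccl22 (-1.06) and Zeb1 (-1.08), the last of which turned to 0.072 when the median of its probe sets was taken.

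Genes outside the induced set also differed under LPS. Tmem87a was 9.89-fold higher in DKO cells, Scd1 5.13-fold, Nectin3 4.01-fold and C1qa 2.86-fold, and the repressor gene Gfi1 was at least 3.93-fold higher. Lower in DKO cells were Spint1 (-2.07), Gsta3 (-2.05), Irf2bpl (-1.98), the haem synthesis gene Cpox (-1.72), Cdk5rap1 (-1.69), Klf4 (-1.59), the cathepsin gene Ctsk (-1.58), Cd24a (-1.55) and the chemokine receptor gene Ccr1 (-1.55, or at least 1.33-fold lower by its other probe set, under the floor in DKO cells). Of 17 named genes past 2-fold with another probe set above the floor on both arrays, 6 had such a probe set short of 2-fold, namely Cd40 (1.90-fold), Rgs16 (1.46-fold), Irf2bpl (1.95-fold lower), Cpox (1.73-fold lower), Ccr2 (1.42-fold lower) and Zeb1. The other probe set of Scd1 gave at least 1.97-fold. Of 11236 genes above the floor, 95 were higher and 105 lower, or 25 and 23 among genes with a mean of at least 500 units.

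**Figure D2:**
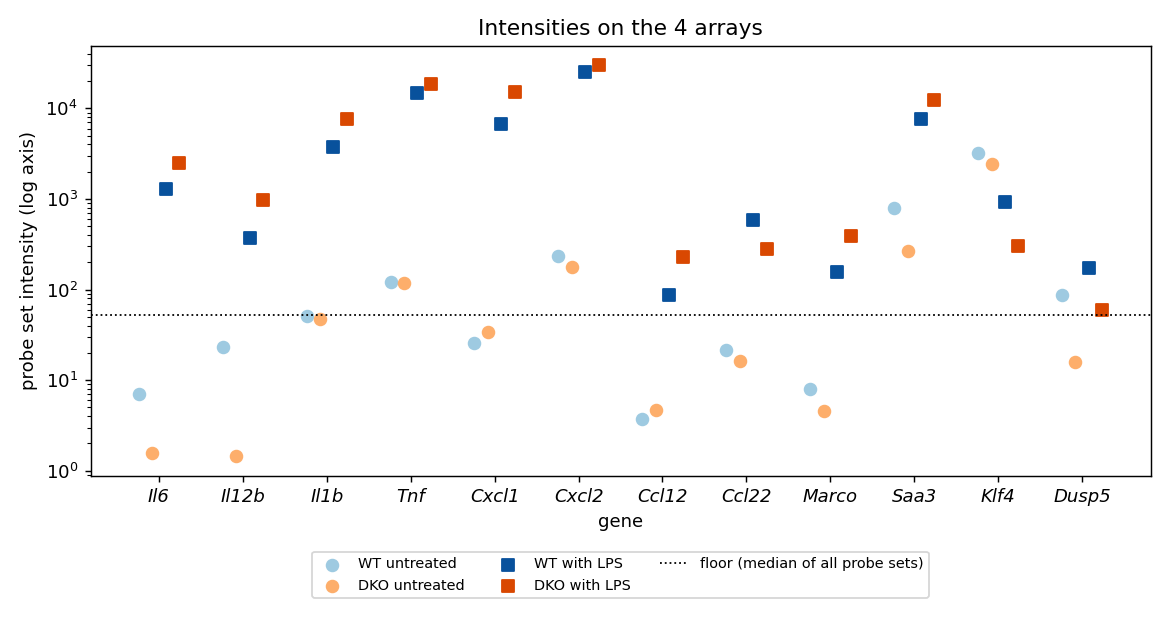
Probe set intensity (y axis, log scale) of 12 genes on the 4 arrays, 1 point per array; circles are untreated cells, squares cells with LPS, blue WT and orange DKO, and the dotted line is the floor of 52.9 units. With LPS, the DKO squares lie above the WT squares for genes such as Il12b (971 against 375) and below for Ccl22 (283 against 589), Klf4 and Dusp5.

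The cytokine list had a median of 0.43 in DKO against WT cells with LPS, against -0.23 to 0.14 for random lists, and 2 of 15 members were higher, Il12b and Il1b. Chemokines had a median of 0.28 against -0.17 to 0.11. Of 19 members 3 were higher, Ccl12, Cxcl1 and Cxcl9 (at least 2.03-fold), and 1 lower, Ccl22. NF-kB feedback regulators stood at 0.21 against -0.13 to 0.058, where none of 27 was higher and 1 lower, the phosphatase gene Dusp5 (-1.53). Interferon-stimulated genes stood at 0.29 against -0.10 to 0.047, with 1 of 40 higher, Mx2 (3.91-fold). Antimicrobial effectors stood at 0.16 against -0.12 to 0.077 with 1 of 24 higher, Marco, and Toll-like receptor signalling at 0.10 against -0.13 to 0.065 with 1 of 27 higher, Tlr1 (2.17-fold).

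The LXR list stood at 0.31 under LPS against -0.16 to 0.11, the alternative activation list at 0.19 against -0.15 to 0.10 with 2 higher and 1 lower of 17, and macrophage identity genes at 0.087 against -0.092 to 0.045, with C1qa higher and Ccr2 lower (-1.09). Beside these, progenitor markers had a median of -0.58 in the same comparison. Immediate early genes gave 1 higher and 3 lower of 22, the lower ones Klf4, Fos (-1.12) and Bhlhe40 (-1.01). Cell cycle genes stood at -0.20 against -0.11 to 0.055, with none of 26 passing 2-fold. Trib3 was lower here too (-1.37). No member passed 2-fold among 30 Notch pathway genes (median 0.020), 16 cholesterol synthesis genes (-0.15), 19 glycolysis and hypoxia genes (-0.045) and 11 Nrf2 targets (0.006).

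**Figure D3:**
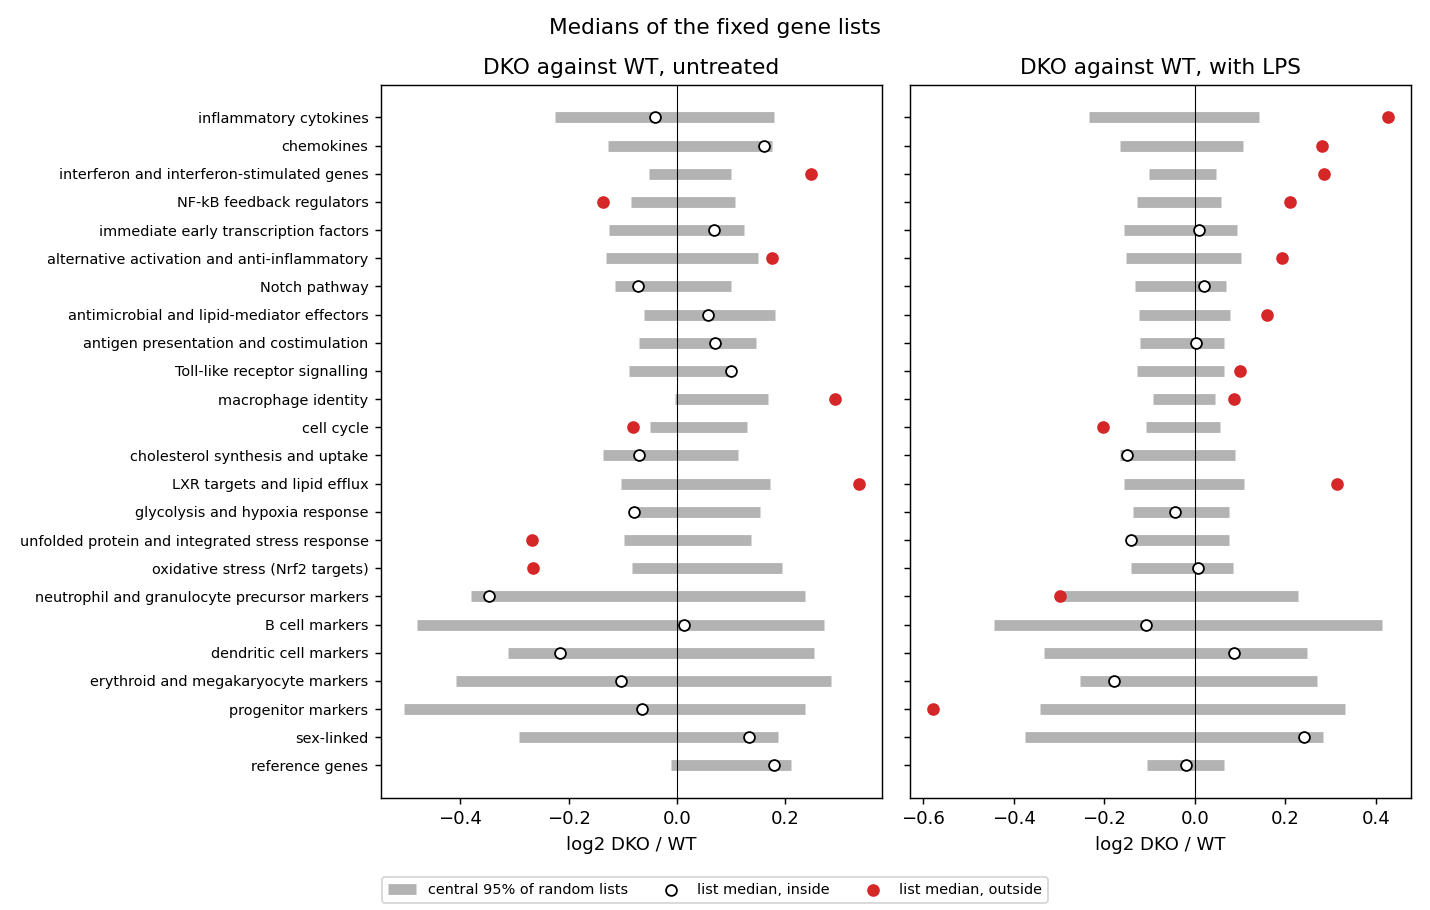
Medians of log2 DKO to WT over the members of each fixed gene list with at least 3 measured members in every comparison, untreated (left) and with LPS (right); grey bars span the central 95% of random lists of equal size matched on expression. Cytokines lie inside the bar untreated (-0.041) and outside it with LPS (0.43), and NF-kB feedback regulators lie below it untreated, at -0.14, or 0.076 against a bar from 0.13 to 0.32 with array medians set equal (not shown), and above it with LPS.

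Some differences between the genotypes appeared with and without LPS. Higher in DKO cells in both treatments were 26 genes, from 53 and 75 among 10787 genes above the floor in both comparisons, where independent lists would share 0.37. Lower in both were 22, from 110 and 102, where independent lists would share 1.04. Across 9982 genes the genotype differences in the 2 treatments correlated with Pearson's r of 0.32 and Spearman's rho of 0.25, and the comparisons share no array. Whether the untreated and LPS arrays of a genotype came from the same animal is not given in the sources used here. A difference between animals or preparations could therefore recur in both treatments, and the overlap is no replicate of the genotype.

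**Figure D4:**
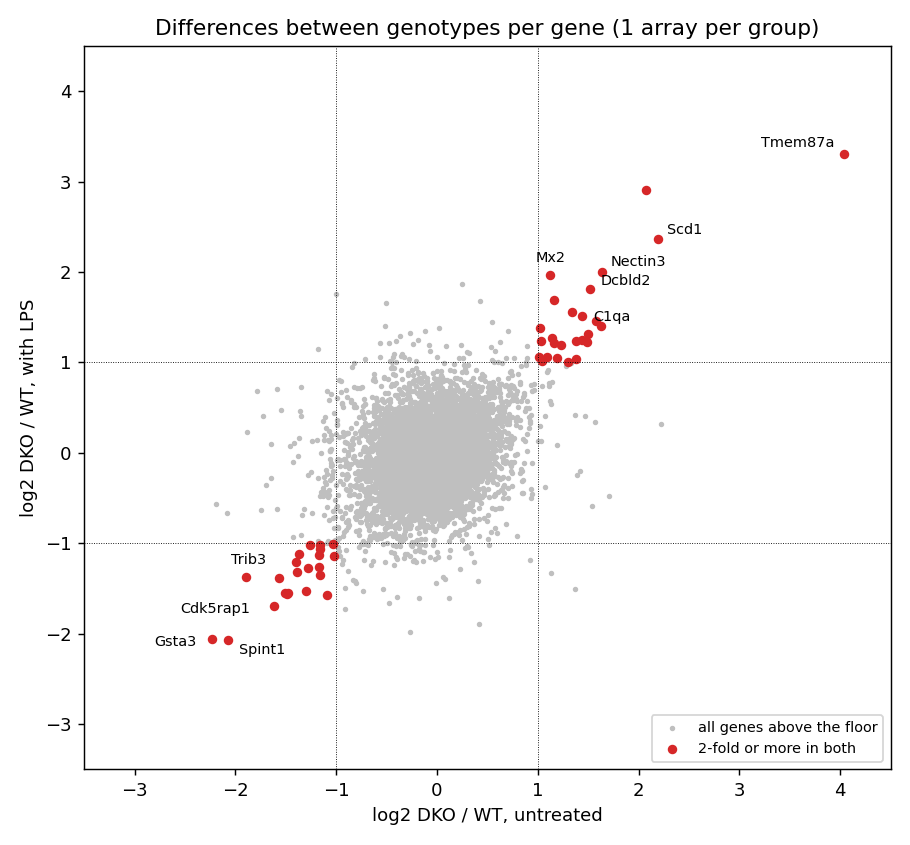
Each point is a gene, with the log2 ratio of DKO to WT without LPS on the x axis and with LPS on the y axis, from 1 array per group; red points passed 2-fold in the same direction in both and dotted lines mark 2-fold. Tmem87a lies farthest to the upper right, at 4.04 and 3.31, and Gsta3 and Spint1 to the lower left.

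The difference of LPS effects, the log2 effect in DKO minus that in WT cells, asks whether the genotypes respond to LPS to different degrees. Over 434 genes induced at least 2-fold on the average of both genotypes, the median LPS effect was 1.45 in WT and 1.84 in DKO cells. The median of the differences was 0.36, with quartiles of 0.099 and 0.64, against -0.074 to -0.012 for the central 95% of matched random lists. The effect was larger in DKO cells for 362 of the 434 genes (83.4%). With array medians set equal, the median difference fell to 0.13, against -0.28 to -0.22 for random lists, and the share to 65.8%. In the 434 genes the median of DKO against WT was 0.25 with LPS and -0.039 without. With LPS, 25 of them were 2-fold higher and 4 lower in DKO cells.

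Genes lowered by LPS, 402 by the same rule, had median effects of -1.14 in WT and -1.41 in DKO cells. Their median difference was -0.35, with quartiles of -0.62 and 0.022, against -0.058 to 0.022 for random lists, and the effect was larger in DKO cells for 297 of them (73.9%). Choosing genes by 1 genotype uses a term of the difference itself and pushes it up for WT (0.16) and down for DKO (-0.46). For genes with 2 probe sets above the floor on all arrays, chosen on the brightest and measured on the second brightest, the medians were close, at -0.16 over 129 genes chosen by WT alone, -0.17 over 182 by DKO alone and -0.20 over 147 by both. Induced genes measured this way gave 0.46, 0.45 and 0.47.

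Among genes above the floor on all arrays, the largest differences included those of Plpp1 (2.75), Sema6c (2.48), Rap1gap (2.33) and Saa3 (2.29), which read 805 and 7661 units in WT cells and 268 and 12486 in DKO cells without and with LPS. At the other end were Nanos1 (-2.18), the mitochondrial alanyl-tRNA synthetase gene Aars2 (-2.12), Sh3tc1 (-1.91) and Irf2bpl (-1.71, and -0.66 by its other probe set). Several of these rest on values just over the floor. Without and with LPS, Sema6c read 210 and 60.7 units in WT cells and 60.7 and 97.6 in DKO cells. In the same order Aars2 read 62.2, 139, 181 and 92.7. Dim genes scattered more: the 95th percentile of absolute differences was 1.01 under a mean of 500 units and 0.58 from 500 units up. Of 9982 genes above the floor on all arrays, 131 had an LPS effect at least 2-fold higher in DKO cells and 72 one at least 2-fold lower. With values under the floor set to it, which gives no bound for a difference of 2 effects, the counts were 218 and 100 of 11829 genes, or 34 and 14 among genes with a mean of at least 500 units. The split of all counted genes was 139 and 219 with array medians set equal, 168 and 121 after quantile normalization, and 174 and 132 after loess, and equal medians moved the median of all genes from -0.028 to -0.23.

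By list, the difference of LPS effects had a median of 0.50 for cytokines against -0.22 to 0.22 for random lists, 0.45 for antimicrobial and lipid-mediator effectors against -0.20 to 0.093, 0.39 for NF-kB feedback regulators against -0.17 to 0.065 and 0.25 for chemokines against -0.19 to 0.14. Only 7 of the 15 cytokines, 13 of the 19 chemokines and 16 of the 24 effectors were above the floor on an untreated array. For the others the difference equals that of DKO against WT with LPS, as for Il12b (1.37), and adds nothing to it. In these lists, the differences of Acod1 (1.22), Cxcl10 (1.32) and Saa3 include lower untreated levels in DKO cells. Stress response genes stood at 0.10 against -0.20 to 0.079, or at -0.11 against -0.41 to -0.12 with array medians set equal, which lowers all genes here, with Chac1 at 1.37 and Slc7a11 at 1.12. Interferon-stimulated genes stood at 0.11 against -0.14 to 0.027 or, with array medians set equal, at -0.079 against -0.35 to -0.18. The Notch pathway stood at 0.087 against -0.15 to 0.087 or, with array medians set equal, at -0.11 against -0.34 to -0.088, inside the range. Immediate early genes stood at -0.23 against -0.19 to 0.13, with Klf4 at -1.20.

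Markers of other cell types that a marrow culture could hold were under the floor for most members of most lists. The erythroid and megakaryocyte list and the progenitor list were exceptions, with 7 of 11 matched members measured in each. Some markers were bright. With LPS, Il7r of the T and NK cell list read 9522 units in WT and 5610 in DKO cells, and the megakaryocyte marker Pf4 5869 and 6690. In DKO against WT cells with LPS, the measured members and their medians were 6 for neutrophils and granulocyte precursors (-0.30), 4 for B cells (-0.11), 3 for T and NK cells (-0.20), 7 for dendritic cells (0.087), 7 for erythroid cells and megakaryocytes (-0.18), 4 for fibroblasts and endothelium (0.31) and 7 for progenitors (-0.58). Of mast cell and basophil markers 2 were measured, too few for a median, and neither passed 2-fold. The progenitor list lay below its random range of -0.34 to 0.33, with 2 members lower, Cd34 (-1.27) and Gfi1b (-1.15), and 1 higher, Gfi1. The neutrophil list lay just below its range of -0.29 to 0.23, and its median turned to 0.11 with a floor at the 65th percentile. In untreated DKO against WT cells the progenitor list had a median of -0.064, inside its range of -0.50 to 0.24, with 1 of 6 members lower, Cd34 (-1.28). For the LPS effect in DKO cells, 8 progenitor markers stood at -0.67 against -0.55 to 0.33. There, 4 fibroblast and endothelial markers stood at 0.61 against -0.79 to 0.51, a sign that changed with other floors. For the LPS effect in WT cells, 7 erythroid and megakaryocyte markers stood at 0.38 against -0.44 to 0.25.

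Signs of RNA quality were close on all arrays. The ratio of the 3' to the 5' control probe set of Gapdh was 0.840, 0.869, 0.850 and 0.877, and that of actin 1.06, 1.11, 1.01 and 1.07, in the order untreated WT, WT with LPS, untreated DKO and DKO with LPS. The 3 control probe sets for 18S ribosomal RNA were brighter on the DKO arrays by a median log2 ratio of 0.63, and hybridisation controls by 0.071. The reference genes had a median of 0.18 without LPS and -0.020 with LPS in DKO against WT cells. The sex-linked list had a median of 0.24 with LPS, inside its random range of -0.38 to 0.28.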

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

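All tests of explanations in this part were chosen after the results were seen, and the requirement of a differing gene within the nearest 50 measured genes was added after the count around Hes1 was known, which changed that test from one that fitted a carried segment to one that leaves it open. For the larger LPS effects, the test with genes chosen on 1 probe set and measured on another was added after other choices had given values of both signs, and the labels of that pattern's tests, first decided and then left open under stricter requirements, became decided again. The limit to other probe sets above the floor on all arrays was likewise added after their values were known, and it changed a test from open to decided for 10 genes.

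Rap1gap and Rnpc3 moved in opposite directions with LPS in the 2 genotypes, each at least 2-fold, and no test of the difference was possible. Rap1gap read 139 and 62.5 units without and with LPS in WT cells and 61.1 and 138 in DKO cells, a difference of LPS effects of 2.33. Rnpc3 read 581 and 286 in WT cells and 228 and 474 in DKO cells, a difference of 2.08, against 0.41 by its other probe set. The dendritic cell markers had a median LPS effect of -0.13 in WT and 0.16 in DKO cells over 7 measured members, also untested, and both medians lay inside their random ranges. The control probe sets for 18S ribosomal RNA, which no comparison used, were brighter on the DKO arrays by a median log2 ratio of 0.63 over 3 probe sets, or 1.55-fold, while hybridisation controls differed by 0.071.

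LPS effects were larger on the DKO arrays than on the WT arrays. Different scaling, or the brighter dim values of the untreated WT array, would move induced and lowered genes the same way, but on the second brightest probe set of genes chosen by WT alone on the brightest, after loess, the median difference was 0.41 over 161 induced genes, against -0.046 to 0.082 for random lists, and -0.22 over 94 lowered genes, against -0.072 to 0.10. Over 24 settings of scaling, brightness and choice by WT, DKO or both, induced genes gave 0.18 to 0.47 and lowered genes -0.49 to -0.16, always beyond the random range on their own side, which argues against scaling as the whole cause and, by the lowered genes, against an effect on induced genes alone, for genes with 2 probe sets above the floor on all arrays. The size still depends on scaling, since with array medians set equal the induced genes on their brightest probe set gave 0.13, against -0.28 to -0.22. A response of the DKO cells that was stronger or further advanced as a whole would give both signs. Both were known before this prediction was written, so they are no separate support for it, and it stays open. A compression of the WT arrays that follows intensity alike for all probe sets would be evened out by quantile normalization. There, the second brightest probe sets of genes chosen by WT alone still gave 0.37 over 156 induced and -0.21 over 104 lowered genes. The random ranges were -0.055 to 0.072 and -0.072 to 0.087. This argues against such a compression as the whole cause for these genes, and other kinds of compression were not tested. An effect of the genotype stays open, since each group was 1 array and the number of cultures is not given in the sources used here.

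Among 48 genes at least 2-fold different between genotypes in both treatments, 5 lie in a window around Hes1, namely Nectin3, Dcbld2, Tbc1d23, Rpl39l and Mx2. The window took up to 300 measured genes on either side in the gene order of GRCm38.p6. It held 369, so it was cut short by an end of the chromosome. It is a wide stretch and not the close surroundings of the locus: Rpl39l has 126 and Mx2 198 measured genes between it and Hes1. On other chromosomes 1.47% of windows held as high a share, although the highest held 7. The genes of that window were not followed up, so linked differences away from Hes1 and Hey1 are left open. DNA of another strain carried along beside the targeted locus is a candidate explanation, but none of the 5 lies within the nearest 50 measured genes on either side, the closest being Nectin3 with 89 between, so it cannot be told apart from a regulated group of genes. Around Hey1 the window of the same rule held 305 genes and 2 of the 48, Fcrls and Ctsk, with 164 and 288 measured genes between. Of windows elsewhere 15% held as high a share, which leaves a carried segment there open as well. A sequence difference under the probes would affect single probe sets, but of 12 other probe sets above the floor on all arrays, from 10 of the 48 genes, 10 (0.833) differed by at least 1.5-fold in the same direction in both treatments. This argues against it for these genes except Siglec1 and Tbc1d23, and leaves it open for the other 38. It holds only where the probe sets of a gene read separate stretches, which was not checked.

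Dim probe sets were brighter on the untreated WT array. Over 19615 probe sets under the floor on all arrays its median log2 ratio to the other arrays was 0.24. Over 16053 probe sets neither under the floor nor at least 500 units on all arrays it was 0.23. A raised background or the scaling of that array predicts the value under the floor, and may explain why its comparisons change with scaling. A background added evenly would move the brighter of these groups less. Scaling by a single factor would also move probe sets of at least 500 units, which stood at 0.015. Neither by itself predicts all these values. Transcripts that LPS lowers would also raise the untreated DKO array, which stood at -0.081 under the floor and 0.054 over the 16053 probe sets. A property of untreated WT cells alone stays open, as no second array of that group was analysed.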

How the results depend on the processing

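The counts limited to genes with a mean of at least 500 units, the values for genes of at least 200 units after loess chosen by WT alone, that for induced genes of at least 200 units with array medians set equal, and those measured on the second brightest probe set, were added after seeing the data, and the other alternatives were planned. Leaving out an array could not be run because it removes a group. The groups, of 1 array each, share no replicate numbers that would pair them, and a fit that takes the treatments as pairs was not run. Dim signal limits the counts: the bacterial controls taken as negative controls reached 46.0 units on the WT array with LPS, against the floor of 52.9, though their medians were 4.64 to 6.87. Except where a value's construction shows it (a lower or higher floor or threshold, fewer genes), the cause of a change was not tested.

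Main counts of genes at least 2-fold higher and lower were 386 and 392 for LPS in WT, 524 and 536 for LPS in DKO, 53 and 112 for DKO against WT untreated, 95 and 105 for the same with LPS, and 218 and 100 for the difference of LPS effects, where 131 and 72 lay above the floor on all arrays. With array medians set equal, LPS in WT gave 194 lower, the untreated genotypes 97 higher and 43 lower, and the difference of LPS effects 139 higher and 219 lower. Quantile normalization gave 256 lower for LPS in WT and 71 lower for the untreated genotypes, and loess gave 223 and 68. A floor at the 35th percentile gave 791 lower for LPS in WT, 799 higher for LPS in DKO, 172 higher and 495 lower for the untreated genotypes, 326 and 318 for the genotypes with LPS, and 822 and 375 for the difference. A floor at the 65th percentile gave 225 lower for LPS in WT, 357 lower for LPS in DKO, 21 and 42 for the untreated genotypes, 37 and 37 with LPS, and 50 and 24 for the difference. With no floor and the offset of 16 units, the untreated genotypes gave 101 higher and 238 lower, the genotypes with LPS 190 and 172, and the difference 474 and 201.

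At a threshold of 1.5-fold the counts were 796 and 1481 for LPS in WT, 1005 and 1632 for LPS in DKO, 269 and 565 for the untreated genotypes, 453 and 565 with LPS, and 823 and 554 for the difference. At 3-fold they were 186 and 65, 277 and 138, 7 and 15, 12 and 10, and 33 and 13 in the same order. Among genes with a mean of at least 500 units, LPS in WT gave 123 lower, LPS in DKO 339 and 226, the untreated genotypes 18 and 29, the genotypes with LPS 25 and 23, and the difference 34 and 14. All other counts stayed within 1.5 times the main ones.

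For genes induced by LPS, the median difference of LPS effects fell from 0.36 to 0.13 with array medians set equal, or 0.075 for genes of at least 200 units with this scaling. It was 0.47 by both genotypes, 0.46 by WT alone and 0.45 by DKO alone for genes chosen on their brightest probe set and measured on the second brightest, and moved by at most 0.1 under the other alternatives. The share with the larger effect in DKO, 83.4%, was 65.8% with equal medians, 79.3% after quantile normalization, 73.6% for genes chosen by WT alone and 89.7% by DKO alone. For genes lowered by LPS, the median of -0.35 turned to 0.16 for genes chosen by WT alone, and was -0.46 by DKO alone, -0.58 with equal medians and -0.12 for genes of at least 200 units after loess chosen by WT alone. A choice by 1 genotype pushes the difference by its construction. Measured on the second brightest probe set of genes chosen on the brightest, the median was -0.20 by both genotypes, -0.16 by WT alone and -0.17 by DKO alone. For the lowered genes of the main rule the share of 73.9% became 41.1% by WT alone, 88.8% by DKO alone, 87.2% with equal medians, 78.2% after quantile normalization, 79.8% after loess and 67.8% with a floor at the 35th percentile.

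Of 995 alternative list medians, 777 stayed within 0.1 of the main value, 208 moved further and 10 changed sign for lists outside their random range. With array medians set equal the sign changed for interferon-stimulated genes (-0.079), the Notch pathway (-0.11) and stress responses (-0.11) in the difference of LPS effects, for NF-kB feedback regulators (0.076) and cell cycle genes (0.13) in the untreated genotypes, and for cell cycle genes with LPS in WT (0.079). This scaling moves all genes of a comparison together, random lists included, and 5 of these 6 lists stayed on the same side of their random range, while the Notch pathway came to lie inside it. With the median of a gene's probe sets the Notch pathway gave -0.035 in the difference. The neutrophil markers gave 0.11 in the genotypes with LPS with a floor at the 65th percentile, and fibroblast and endothelial markers, at 0.61 with LPS in DKO, gave -0.23 with a floor at the 35th and -0.22 at the 65th percentile.

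For LPS in WT, 1 list lay below the central 95% of random lists, and 0 did with the median of a gene's probe sets or with shared probe sets left out. For LPS in DKO the number was 1 and became 2 after quantile normalization, loess, a floor at the 35th percentile or without shared probe sets. For the difference of LPS effects it was 1 and became 0 with array medians set equal or no floor, 3 with a floor at the 35th percentile, and 2 with the median of a gene's probe sets or without shared probe sets. Of 5627 alternative values of named genes, 5312 stayed close to the main value, 314 moved and 1 changed sign, Zeb1 in the genotypes with LPS, at 0.072 with the median of its probe sets.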

Other observations

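The genes named in this part were chosen after their values were seen, except those of the fixed lists. Among the 26 genes higher in DKO cells in both treatments, Folr2 read 11222 against 4304 units without LPS and 10107 against 4930.2 with LPS, in DKO and WT cells in that order. C1qa read 8804 against 3237 and 9145 against 3197. The carbonyl reductase gene Cbr2 differed by log2 values of 1.38 and 1.24, the phospholipid transfer protein gene Pltp by 1.14 and 1.27, and Fcrls by 1.19 and 1.05. The sialic acid receptor gene Siglec1 differed by 1.01 and 1.05, but another probe set above the floor on all arrays gave -0.057 without and 0.47 with LPS.

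Among the 22 genes lower in DKO cells in both treatments, Cd34 differed by -1.28 without and -1.27 with LPS, Cd24a by -1.51 and -1.55, the chemokine receptor gene Ccr1 by -1.48 and -1.55 (its other probe set, under the floor in DKO cells, gives bounds only), and the lectin gene Clec4b1 by -1.39 and -1.32. The glutathione transferase genes Gsta3 and Gstm2 were both lower, Gstm2 by -1.16 and -1.35.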
